A study of Capra hircus with 8 samples.

How the data were processed

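Goat (Capra hircus) embryos were lysed directly and polyadenylated RNA was turned into cDNA libraries by Smart-seq2, a protocol that amplifies full-length cDNA from very few cells. The samples were 8 libraries in 4 groups of 2: embryos made by in vitro fertilisation (IVF) and embryos made by somatic cell nuclear transfer (SCNT), in which the nucleus of a body cell is placed in an egg whose own nucleus was removed, each at the 4-cell and at the 8-cell stage. The labels do not say whether the replicates of a group are separate pools of embryos. The limma p-values therefore measure only the spread between these samples, estimated in part from all tested features. Permutation p-values come from shuffling features and do not measure a spread between samples. Whether the replicate numbers 1 and 2 pair libraries across groups is not given either, and the main tests did not pair them. Across genes, the correlation between the replicate differences of the IVF and the SCNT 8-cell pairs was 0.12 for messenger RNAs. That value does not settle whether the libraries were paired. The series also describes a knockdown of the lncRNA lnc_3712, which was not analysed here.

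The authors deposited 4 tables of FPKM (fragments per kilobase of feature and per 1000000 fragments): messenger RNAs at the 8-cell stage, long non-coding RNAs (lncRNAs) at the 4- and 8-cell stages, annotated lncRNAs at the 8-cell stage, and lncRNAs carrying an lnc_ number at the 8-cell stage. These are called annotated and numbered lncRNAs here. The submitters' processing notes name fastp, HISAT2 2.2.1 and HTSeq without giving a role or an order for each. The genome build, the annotation, the total used for the scaling and the way the numbered lncRNAs were assembled are not given in the sources used here, so no genome coordinates are given. A RefSeq gene table for goat served for gene names, gene types and the order of genes along chromosomes. Of the 22107 names in the messenger RNA table, 22065 were found in it. Another 24 names had been turned into dates, and 281 entries carry a repeated name; neither kind was eligible as a named gene. The messenger RNA table also holds genes of other types, including all 1505 annotated lncRNAs with the same values. The 4- and 8-cell lncRNA table holds 6011 lncRNAs, 1505 annotated and 4506 numbered, and its 8-cell values equal those of the separate tables. It lists annotated lncRNAs by ID; 1291 IDs were paired with a name because their values match a single entry exactly.

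Read counts were not used as such. The number of reads behind the scaling was recovered from the steps between the lowest FPKM values. In units of 1000000 reads (M), it was 26.9 and 28.7 M in the IVF 4-cell libraries, 27.5 and 30.3 M in the IVF 8-cell libraries, 28.9 and 29.2 M in the SCNT 4-cell libraries, and 28.4 and 28.5 M in the SCNT 8-cell libraries. With the ratios between totals, 65% of 1000 genes came to whole reads within 0.01 read in every 8-cell library, against 0.9% with wrong ratios. The genes were drawn at random from those above 0 in most 8-cell libraries. This tests the ratios and not the size of the totals. The size rests on short genes, of which 16 of 24 gave the same total in IVF 8-cell replicate 1. PCR copies of a molecule cannot be told from separate molecules in these libraries.

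The 8-cell messenger RNA table was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the variance on the level) on log2(FPKM + 1), for genes at 1 FPKM or more in at least 2 libraries. The lncRNA tables were tested the same way on log2(FPKM + 0.5), at 0.5 FPKM or more in at least 2 libraries. The 4 groups of the 4- and 8-cell table shared a single fit. A group listed at 0 in both libraries adds no spread to a fit, so the standard errors of such lncRNAs can come out too small. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all features of a comparison, and 0.05 was the threshold. Log2 differences are SCNT minus IVF, or 8-cell minus 4-cell. They are computed after the pseudocount (1 or 0.5 FPKM) is added, so they understate the ratio for genes at low level. No fold is given against a group listed at 0; for the difference between stage changes the fitted value is given, which depends on the pseudocount and is not a fold where a group is at 0.

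Of 32 gene lists fixed beforehand, the 28 with at least 5 tested members were tested with camera, which compares the members of a list with all other genes, at a preset correlation of 0.01 between members. Camera with an estimated correlation and fry were run beside it; fry tests whether the members move, on balance, to 1 side, without comparing them with other genes. The lists cover chromatin enzymes, genome activation, oocyte genes, pluripotency, core cell machinery, stress, imprinting, X-linked dosage, and markers of fibroblasts, cumulus cells, sperm, blood and epithelium. The untested lists were H3K27 demethylases, sperm, blood and somatic epithelial markers. For the members of each list, p-values were adjusted over all genes and again over the list alone.

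Named protein-coding genes were the 12 with the largest log2 difference in each direction, among genes with a symbol, past the threshold, at 1 FPKM or more in both libraries of the higher group, and with no overlap between groups. Named lncRNAs were the 2 in each direction by the same rule; where fewer passed, the rest were filled in by smallest p and are given as values. For annotated lncRNAs, the rule also covered up to 10 per direction with a gene symbol. KDM5B, lnc_3712 and up to 4 members of each list were named whatever their values. This rule, the comparisons, the gene lists, the thresholds and most alternative settings were chosen before the data were examined. The alternatives were other pseudocounts, other filters, centring the libraries on the median log ratio of features at 1 FPKM or more in every library, rescaling to a total of 1000000 (messenger RNAs), quantile normalization, no variance trend, the replicate number as a block, only the 2 compared groups in the fit, and leaving out each library in turn. Library weights, protein-coding genes alone, and lncRNAs above 0 in all 8 libraries were added after seeing the data. When a library is left out, the lone remaining library of its group is assumed to vary like the other group or groups.

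The tests were tried on simulated data made from these tables. For messenger RNAs, 74% of genes changed 4-fold and 98% of genes changed 8-fold were found, and 13 of 199 calls were false. For the 8-cell contrast of the lncRNA table, 38% and 82% were found, with 10 false calls of 160. The simulated noise was independent between features and equal in all libraries, without zeros, and the features of lowest level were not changed. The real SCNT 8-cell replicates differed more than the IVF ones and many lncRNAs have zeros, so these shares may not hold for the real data. Camera called 3 of 100 unchanged lists at an unadjusted p under 0.05. Those lists were drawn at random from genes simulated independently, so this does not give the rate for lists whose members vary together. Figures and read totals were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.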

Results

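Gene expression was measured in 8 goat embryo samples, 2 each of IVF and SCNT embryos at the 4-cell and 8-cell stages, around the time when the embryo begins to transcribe its own genome. Messenger RNA values cover the 8-cell stage alone, and lncRNA values cover both stages. The recovered totals lay between 26.9 and 30.3 M reads per library (M, 1000000). At the 8-cell stage, 8984 and 9038 genes reached 1 FPKM in the IVF libraries and 9883 and 11025 in the SCNT libraries. The 10 most abundant genes held 17.8% and 16.9% of the summed FPKM in IVF and 11.6% and 11.7% in SCNT. Across genes, which are not independent replicates, the 2 IVF 8-cell libraries correlated at r = 0.96 and the 2 SCNT 8-cell libraries at r = 0.90. SCNT 8-cell replicate 2 correlated with the IVF libraries at 0.78 and 0.82, and SCNT 8-cell replicate 1 at 0.89 and 0.91. Between replicates, the median absolute log2 difference was 0.30 in IVF and 0.63 in SCNT.

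The first comparison asked how messenger RNAs of 8-cell SCNT embryos differ from those of fertilised embryos. In SCNT embryos, PI3, which encodes the elastase inhibitor elafin, stood at 384 ± 334 against 2.04 ± 2.05 FPKM (SD, n = 2) in IVF embryos, a log2 difference of 6.83 ± 0.73 (SE). The chemokine receptor gene CCR7 rose by 5.10 (45.8 ± 21.2 against 0.326 ± 0.436 FPKM) and TKT, the transketolase of the pentose phosphate pathway, by 4.96 (65.0 ± 1.94 against 1.2 ± 0.795 FPKM). The Wnt ligand gene WNT16 fell by 3.71 on the log2 scale, from 51.9 ± 0.199 to 3.39 ± 2.42 FPKM, and HMGN5, which encodes a nucleosome-binding protein, fell by 3.30, from 14.9 ± 2.96 to 0.607 ± 0.148 FPKM. Their adjusted p-values in limma were 0.016 for PI3, 0.014 for CCR7 and TKT, and 0.022 for WNT16 and HMGN5.

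Other genes with a symbol and large rises included FOS (log2 difference 4.49), a subunit of the AP-1 transcription factor, LRRC58 (4.30), SCPEP1 (4.18), the autophagy receptor gene SQSTM1 (4.02), the oocyte homeobox gene SEBOX (3.93), ZNF576 (3.78) and the phosphate transporter gene SLC34A2 (3.51). The other genes with the largest falls, among protein-coding genes with a symbol that met the naming rule, were C1D (−3.25), DNAJC12 (−3.04), the prostaglandin-degrading enzyme gene HPGD (−2.98), RSRP1 (−2.97), SETD9 (−2.60), OLR1 (−2.59), KIAA0101 (−2.47), RFLNB (−2.46), SRGN (−2.45) and FAM133A (−2.43). For the 24 genes with a symbol named by that rule, 12 in each direction, passing depended on which library was left out. Without SCNT 8-cell replicate 1 the spread came from the closer IVF pair alone, so a call kept there says little. Without SCNT 8-cell replicate 2, 7 passed, among them CCR7, TKT, FOS, SCPEP1, WNT16 and SETD9. PI3 (0.0610) and HMGN5 (0.0620) were among the genes that did not.

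Of 10303 genes tested, 398 passed, 311 higher and 87 lower in SCNT embryos, with 3200 genes at an unadjusted p under 0.05. The median log2 difference over all tested genes was 0.39 as deposited, 0.12 after median centring, 0.44 after rescaling to a total of 1000000 and −0.01 after quantile normalization. The calls were 172 higher and 109 lower after centring, 1133 and 194 after rescaling, and 121 and 150 after quantile normalization. The count also depended on single libraries. It was 3834 without SCNT 8-cell replicate 1, 46 (13 higher, 33 lower) without SCNT 8-cell replicate 2, 173 without IVF 8-cell replicate 1 and 257 without IVF 8-cell replicate 2.

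**Figure D1:**
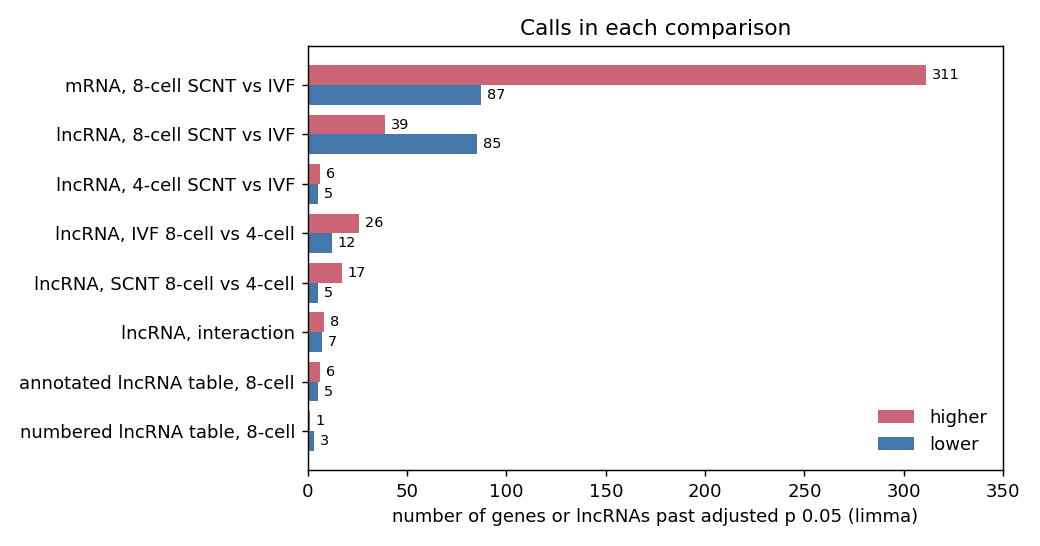
Number of genes or lncRNAs past an adjusted p of 0.05 in limma in each comparison (horizontal axis), higher in red and lower in blue, in SCNT against IVF or at 8 cells against 4 cells. At the 8-cell stage, 311 genes of all types were higher and 87 lower in SCNT as deposited (121 and 150 after quantile normalization). With protein-coding genes alone tested, 463 were higher and 72 lower. In the lncRNA comparison, 39 were higher and 85 lower (40 and 35 after quantile normalization).

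KDM5B, the histone H3 lysine 4 (H3K4) demethylase in the title of the series, stood at 3.91 and 1.51 FPKM in the 2 SCNT libraries and at 0.498 and 0.846 FPKM in the 2 IVF libraries. Both SCNT values lay above both IVF values. The log2 difference of 1.08 ± 0.43 (SE) did not pass (adjusted p = 0.135), and no alternative that gave a value changed this (adjusted p from 0.0909 to 0.601). It was 0.60 without SCNT 8-cell replicate 1 and 1.56 without SCNT 8-cell replicate 2. Among the other tested H3K4 demethylases, KDM1A had 79.7 ± 10.7 against 26.8 ± 7.12 FPKM (adjusted p = 0.063), KDM5A 7.88 ± 0.442 against 2.11 ± 0.411 FPKM (0.070), KDM5C 1.30 ± 0.0832 against 0.0956 ± 0.0107 FPKM (0.067) and KDM1B 33.3 ± 16.6 against 38.6 ± 0.923 FPKM (0.696). None of the 5 passed over all genes. Adjusted over the list alone, 4 passed, all but KDM1B, and the list as a whole did not pass (camera adjusted p = 0.408).

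**Figure D2:**
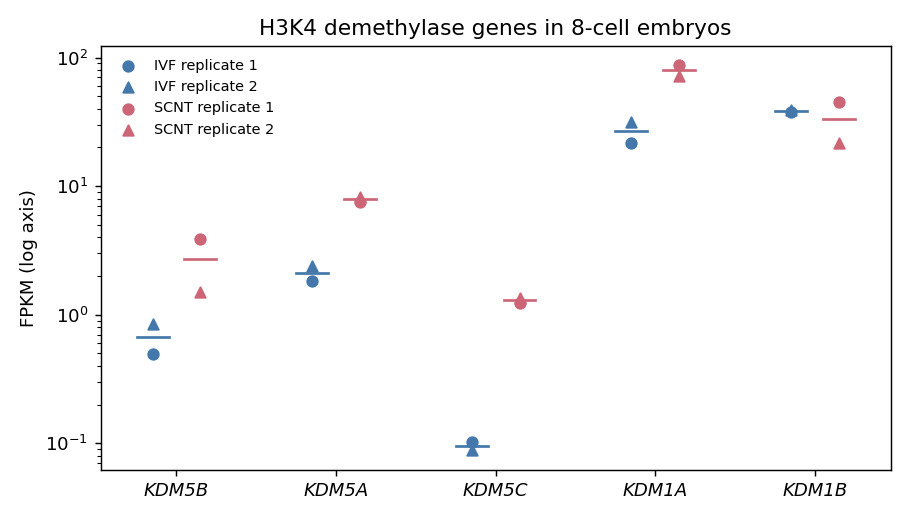
FPKM on a log axis of 5 H3K4 demethylase genes in 8-cell IVF and SCNT embryos; each point is a library and each short line the mean of 2 libraries. KDM5B lay at 0.498 and 0.846 FPKM in IVF and at 3.91 and 1.51 FPKM in SCNT, and KDM1B at 37.9 and 39.2 FPKM in IVF and at 45 and 21.6 FPKM in SCNT.

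Of the 28 gene lists tested, 3 passed, all higher in SCNT than the other genes. None of the 3 passed with an estimated correlation (adjusted p = 0.893 for each) or in fry. Oocyte and maternal-effect genes had a median log2 difference of 0.87 (camera adjusted p = 0.045): of 40 tested, 4 rose, none fell and 36 did not pass. They were ASTL, the protease that hardens the egg coat after fertilisation (39.0 ± 5.83 against 4.61 ± 1.86 FPKM), ZAR1L (1174 ± 553 against 189 ± 8.11 FPKM), KHDC3L (93.3 ± 8.23 against 22.6 ± 5.33 FPKM) and NLRP13 (79.5 ± 35.5 against 15.7 ± 7.39 FPKM). Glycolysis genes had a median of 1.49 (0.045): of 15 tested, 4 rose and 11 did not pass. These were the enzyme genes ENO1 (61.3 ± 32.3 against 5.18 ± 1.04 FPKM) and PKM (47.6 ± 25 against 7.10 ± 1.54 FPKM) and the glucose transporter genes SLC2A1 (26.9 ± 3.95 against 3.36 ± 1.52 FPKM) and SLC2A3 (133 ± 84.5 against 21.3 ± 9.85 FPKM). Ribosome biogenesis genes had a median of 0.91 (0.038): of 47 tested, 2 rose and 45 did not pass. The 2 were RRP9 (8.66 ± 5.44 against 0.782 ± 0.0519 FPKM) and RRP1 (14.3 ± 8.76 against 1.65 ± 0.187 FPKM). Adjusted over the list alone, 15 oocyte, 5 glycolysis and 11 ribosome biogenesis genes rose. ASTL, ZAR1L, ENO1 and SLC2A1 kept their calls after median centring and after quantile normalization, and KHDC3L, NLRP13, PKM, SLC2A3, RRP9 and RRP1 lost them under both. The adjusted p-values in fry were 0.120, 0.176 and 0.0613. The medians of the 3 lists lay above that of all genes under each of the 3 other scalings. Centring and rescaling move all genes of a library alike apart from the pseudocount, so they could hardly change this order.

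These 3 lists moved with single libraries. Without SCNT 8-cell replicate 2, ribosome biogenesis passed (adjusted p = 0.00197), and oocyte genes (0.108) and glycolysis (0.268) did not. Without SCNT 8-cell replicate 1, glycolysis alone passed (0.0156). Without IVF 8-cell replicate 1, 7 lists passed, these 3 and genome activation (0.00242), ribosomal proteins (0.00378), proteasome (0.00987) and histone deacetylases (0.0426). Without IVF 8-cell replicate 2, oocyte genes (0.0151), glycolysis (0.0321) and ribosomal proteins (0.0151, lower than the other genes) passed and ribosome biogenesis did not (0.0540). SCNT 8-cell replicate 2 exceeded replicate 1 by a median of 1.15 in glycolysis genes, 0.53 in oocyte genes and 0.23 in ribosome biogenesis genes. Over all tested genes the median was 0.25. Oxidative phosphorylation (0.90) and ribosomal proteins (0.83), which did not pass with all libraries, had larger gaps than the oocyte genes. GAPDH, the glycolytic enzyme gene often used as a reference, stood at 109 and 527 FPKM in SCNT replicates 1 and 2 and at 84.5 and 85.4 FPKM in IVF (adjusted p = 0.167).

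**Figure D3:**
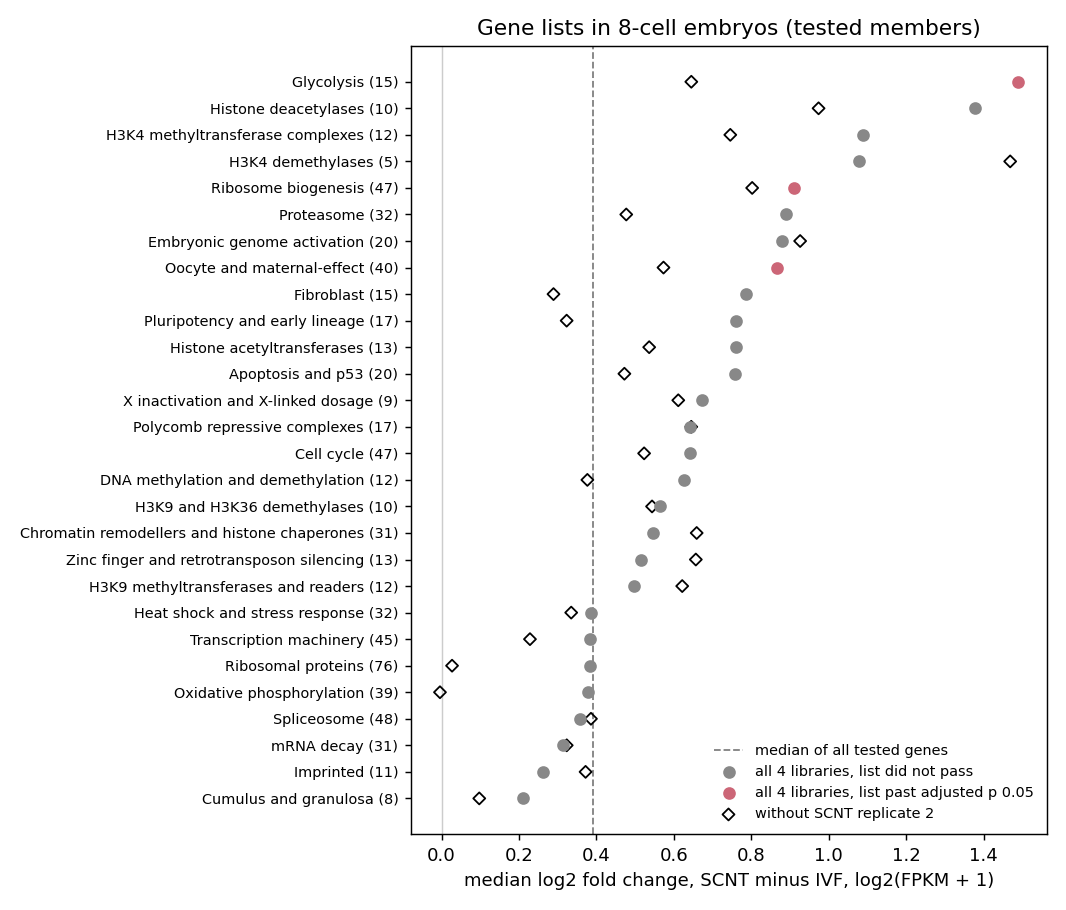
Median log2 difference, SCNT minus IVF, of the tested members of 28 gene lists in 8-cell embryos (number of members in parentheses), with all 4 libraries (filled circles, red where the list passed in camera at the preset correlation; none passed with an estimated correlation) and without SCNT replicate 2 (open diamonds). Glycolysis lay at 1.49, ribosome biogenesis at 0.91 and oocyte and maternal-effect genes at 0.87, against a median of 0.39 over all tested genes (dashed line, −0.01 after quantile normalization).

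In the other lists, 34 different genes passed over all genes when those above are included, and each of them rose. After median centring 16 of the 34 passed, after quantile normalization 11 and after rescaling all 34. Without SCNT 8-cell replicate 2, ZAR1L and FOS were the only list members that passed. Fewer of the 34 also passed without either IVF 8-cell replicate. Without SCNT 8-cell replicate 1 the spread came from the closer IVF pair alone, so a call kept there says little. Among chromatin lists, 2 of 31 chromatin remodellers and histone chaperones rose, the histone chaperone genes ASF1B (184 ± 55.9 against 22.7 ± 11.3 FPKM) and CHAF1A (54.6 ± 20.5 against 11 ± 4.76 FPKM), with 4 adjusted over the list alone. TRIM28, the corepressor of zinc finger proteins, rose among 12 H3K9 methyltransferases and readers (12.1 ± 3.31 against 1.03 ± 0.0142 FPKM; 3 adjusted over the list alone). ZFP57, a guard of imprinted methylation, rose among 12 DNA methylation genes (4.15 ± 0.797 against 0.225 ± 0.302 FPKM; 1 adjusted over the list alone), in which DNMT1 stood at 241 ± 46.8 and 216 ± 0.897 FPKM (adjusted p = 0.831). The histone acetyltransferase gene KAT2A rose among 13 (23.5 ± 10.9 against 3.78 ± 1.07 FPKM; 1 adjusted over the list alone). After median centring and after quantile normalization, ASF1B and TRIM28 kept their calls and CHAF1A and KAT2A lost them, while ZFP57 lost its call after quantile normalization alone. None passed among 12 genes of H3K4 methyltransferase complexes, 10 H3K9 and H3K36 demethylases, 17 Polycomb genes, 10 histone deacetylases and 13 genes of zinc finger and retrotransposon silencing. Adjusted over the list alone, 2, 2, 2, 5 and 0 of them rose. The single H3K27 demethylase tested, KDM6A, had 1.66 ± 0.888 against 0.620 ± 0.00378 FPKM (adjusted p = 0.247).

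Among 20 genes of embryonic genome activation, 1 rose, SLC34A2 (23.5 ± 7.35 against 1.09 ± 0.114 FPKM), 0 fell and 19 did not pass; 6 rose adjusted over the list alone. Among the homeobox genes of this list, ARGFX stood at 497 and 105 FPKM in IVF and 51.4 and 88.3 FPKM in SCNT (adjusted p = 0.128), DUXA at 297 and 46.1 and at 78.8 and 74.6 FPKM (0.609), and LEUTX at 577 and 372 and at 160 and 499 FPKM (0.418). None of 17 pluripotency and early lineage genes passed, over all genes or adjusted over the list alone. POU5F1 had 18.3 ± 10.2 against 5.71 ± 0.619 FPKM (0.107) and NANOG 6.51 and 25.3 FPKM in SCNT and 17.3 and 2.76 FPKM in IVF (0.561). None of 31 mRNA decay genes, 11 imprinted genes or 9 genes of X inactivation and X-linked dosage passed over all genes. Adjusted over the list alone, 2 of the X list rose and 0 of the other lists.

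In the core machinery, 5 of 32 proteasome genes rose, PSMD13, PSMB5, PSMD8, PSMD3 and ADRM1, with 7 adjusted over the list alone. PSMB5, a catalytic subunit, had 178 ± 102 against 31.7 ± 3.79 FPKM. The splicing genes SNRPB (25.3 ± 18.8 against 1.72 ± 1.73 FPKM) and SNRPA (115 ± 53.8 against 24.2 ± 1.56 FPKM) rose among 48, with 6 adjusted over the list alone. Of 39 oxidative phosphorylation genes, 1 rose, and 2 adjusted over the list alone. None of 76 entries with ribosomal protein names and 45 genes of the transcription machinery passed, over all genes or adjusted over the list alone. Of the 76, RPL37A is an entry that the authors also list among annotated lncRNAs. The calls of PSMD13, PSMB5, PSMD8, PSMD3, ADRM1, SNRPB and SNRPA were lost after median centring and after quantile normalization. MCM5, part of the replicative helicase (43.1 ± 24 against 5.16 ± 1.35 FPKM), and CDC20, an activator of the anaphase-promoting complex (110 ± 55.2 against 17.9 ± 9.87 FPKM), rose among 47 cell cycle genes, with 4 adjusted over the list alone. Among 20 apoptosis and p53 genes, 3 rose, among them BAD and the p53 target CDKN1A (5.99 ± 4.82 against 0.130 ± 0.0115 FPKM for CDKN1A), and 3 rose adjusted over the list alone. MCM5, BAD and CDKN1A lost their calls after quantile normalization, and CDC20 also after median centring. CHAC1, a glutathione-degrading enzyme gene (35.3 ± 11.4 against 2.48 ± 0.202 FPKM), and FOS rose among 32 heat shock and stress genes, also adjusted over the list alone, and kept their calls after median centring and after quantile normalization.

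Markers of other cell types were tested because SCNT embryos start from a somatic nucleus and recipient eggs are taken from among cumulus cells. Of 15 fibroblast markers, TIMP1 (12.1 ± 1.22 against 0.397 ± 0.340 FPKM) and TAGLN (4.90 ± 0.0635 against 0.524 ± 0.190 FPKM) rose and 13 did not pass. Adjusted over the list alone, 4 rose and DCN, the proteoglycan decorin, fell (36.7 ± 3.98 against 89.9 ± 6.21 FPKM). None of 8 cumulus and granulosa markers passed, over all genes or adjusted over the list alone. Of 4 tested epithelial markers, KRT8, KRT5, CDH1 and EPCAM, the keratin gene KRT8 rose (16.8 ± 11.6 against 1.07 ± 1.46 FPKM), and 2 rose adjusted over the list alone. After quantile normalization KRT8 and TAGLN lost their calls, KRT8 also after median centring. The single sperm marker tested was ODF2 (25.3 ± 9.74 against 9.26 ± 2.42 FPKM; adjusted p = 0.105), and no blood marker was high enough to be tested.

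The next comparison asked which lncRNAs differ between 8-cell SCNT and IVF embryos. Of the numbered lncRNAs, lnc_751 was listed at 106 and 68.7 FPKM in SCNT and at 0 in both IVF libraries. In the opposite direction, lnc_750 was listed at 67.8 and 106 FPKM and lnc_1448 at 54.9 and 80.5 FPKM in IVF, and both at 0 in SCNT (adjusted p = 0.000763 for all 3). The numbers of lnc_750 and lnc_751 follow each other, and each was listed at 0 in exactly those of the 8 libraries in which the other was above 0. Another lncRNA, lnc_2621, rose from 0.0957 ± 0.0463 to 20.5 ± 8.53 FPKM (log2 difference 5.08 ± 0.52 SE, adjusted p = 0.0143). Of 2611 lncRNAs tested, 124 passed, 39 higher and 85 lower in SCNT, with 568 at an unadjusted p under 0.05. The median log2 difference was −0.33 as deposited, −0.05 after centring (45 higher, 58 lower) and 0 after quantile normalization (40 higher, 35 lower). With the 8-cell groups alone in the fit, limma called 0 lncRNAs, with 463 at an unadjusted p under 0.05. The count was 15 without IVF 4-cell replicate 1, 18 without IVF 4-cell replicate 2, and 4 without either SCNT 4-cell replicate; lnc_2621 did not pass without SCNT 4-cell replicate 1 (0.0530) or replicate 2 (0.0541) or with the 8-cell groups alone (0.15), and passed in all other alternatives.

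The lncRNA in the title of the series, lnc_3712, was listed at 0.465 and 0.863 FPKM in SCNT 8-cell replicates 1 and 2 and at 0 in the other 6 libraries. It reached 0.5 FPKM in a single library and was not tested. The smallest whole numbers of reads that give the 2 values, within 0.02 read, are 22 and 41. At that size a single read would be 0.0211 FPKM in SCNT 8-cell replicate 1, and the 0 in IVF 8-cell replicates 1 and 2 would allow up to 0.0655 and 0.0594 FPKM (3 reads, counting error only). Of the 4506 numbered lncRNAs, 945 were above 0 in exactly 2 libraries, and 70 of these in the SCNT 8-cell pair, against 98 in the IVF 8-cell pair, 74 in a pair from different groups (IVF 4-cell replicate 2 and IVF 8-cell replicate 1) and a mean of 33.8 over the 28 pairs of libraries.

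At the 4-cell stage, lnc_2121 was listed at 26.9 and 14.9 FPKM in SCNT and 0 in IVF (adjusted p = 0.0152), and lnc_2645 at 7.35 and 14.9 FPKM in SCNT and 0 in IVF (0.0173). In contrast, lnc_47 was listed at 16.7 and 21.5 FPKM in IVF and 0 in SCNT (0.00860). An annotated lncRNA, LOC108634521 by its identical values, fell from 15.5 ± 5.69 FPKM in IVF to 0.0092 ± 0.0130 FPKM in SCNT (log2 difference −4.93 ± 0.60 SE, 0.0347). In all, 11 of 2611 lncRNAs passed, 6 higher and 5 lower, with 239 at an unadjusted p under 0.05. After median centring 6 were higher and 8 lower. Without IVF 4-cell replicate 2 limma called 0 (164 at an unadjusted p under 0.05). With the 4-cell groups alone in the fit, 3 lncRNAs passed, none of them among the 11. The count was 7 without IVF 4-cell replicate 1, 5 and 7 without SCNT 4-cell replicates 1 and 2, 20 and 24 without IVF 8-cell replicates 1 and 2, and 26 and 27 without SCNT 8-cell replicates 1 and 2. Each of the 4 named lncRNAs lost its call without some library. For lnc_2121 these were IVF 4-cell replicates 1 (0.0727) and 2 (0.154) and SCNT 4-cell replicates 1 (0.0738) and 2 (0.0527), for lnc_2645 IVF 4-cell replicates 1 (0.0727) and 2 (0.159), and for lnc_47 IVF 4-cell replicate 2 (0.0604). LOC108634521 lost its call without IVF 4-cell replicates 1 (0.107) and 2 (0.230), IVF 8-cell replicates 1 (0.0719) and 2 (0.0799) and SCNT 4-cell replicates 1 (0.176) and 2 (0.193).

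The change from 4 to 8 cells was followed in each embryo type. In IVF embryos, lnc_1448 went from 0 to 54.9 and 80.5 FPKM (adjusted p = 0.00229) and lnc_2121 from 0 to 22.2 and 41.5 FPKM (0.0106). In the other direction, lnc_4139 went from 6.78 and 10.5 FPKM to 0 and lnc_1945 from 5.61 and 6.47 FPKM to 0 (0.0106 for both). Of 2611 lncRNAs, 38 passed, 26 higher and 12 lower at 8 cells, with 373 at an unadjusted p under 0.05. The share of higher calls was 68.4% as deposited and 58.1% (18 and 13) after quantile normalization, where the median difference moved from 0.23 to 0. The count was 10 and 4 without IVF 4-cell replicates 1 and 2, 77 and 70 without IVF 8-cell replicates 1 and 2, 9 and 4 without SCNT 4-cell replicates 1 and 2, and 74 and 78 without SCNT 8-cell replicates 1 and 2. The call of lnc_2121 was lost without IVF 4-cell replicates 1 (0.0549) and 2 (0.0828), that of lnc_4139 without IVF 4-cell replicate 2 (0.0762) and SCNT 4-cell replicate 2 (0.0558), and that of lnc_1945 without IVF 4-cell replicates 1 (0.0570) and 2 (0.0871) and SCNT 4-cell replicate 2 (0.0558). The call of lnc_1448 was kept without each of the 8 libraries. With the IVF groups alone in the fit, 1 lncRNA passed, which was none of the 38, and the 4 named ones did not pass (0.135 for each).

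In SCNT embryos, lnc_751 went from 0 to 106 and 68.7 FPKM (adjusted p = 0.00123) and lnc_47 from 0 to 14.9 and 15.6 FPKM (0.00416). Conversely, lnc_750 went from 44.4 and 39.7 FPKM to 0 (0.00123) and lnc_2645 from 7.35 and 14.9 FPKM to 0 (0.0118). Of 2611 lncRNAs, 22 passed, 17 higher and 5 lower at 8 cells, with 242 at an unadjusted p under 0.05; the shares of higher calls were 77.3% as deposited and 65.8% (25 and 13) after quantile normalization. The count was 3 without either IVF 4-cell replicate, 34 without either IVF 8-cell replicate, 9 and 10 without SCNT 4-cell replicates 1 and 2, and 71 and 53 without SCNT 8-cell replicates 1 and 2. The call of lnc_2645 was lost without IVF 4-cell replicates 1 (0.0562) and 2 (0.0626), and the other 3 were kept without each of the 8 libraries. With the SCNT groups alone in the fit, limma called 0 (269 at an unadjusted p under 0.05). The stage change itself differed between embryo types for 15 lncRNAs, with a positive difference (SCNT change minus IVF change) for 8 and a negative one for 7.

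The separate 8-cell tables were tested on their own. Among annotated lncRNAs, LOC108636074 rose from 1.97 ± 0.663 to 21 ± 12.8 FPKM and LOC108634143 from 106 ± 55.8 to 663 ± 380 FPKM (adjusted p = 0.0438 for both), while LOC108634521 fell from 13.8 ± 3.90 to 0.470 ± 0.665 FPKM and LOC102171192 from 9.30 ± 5.34 to 0.0901 ± 0.127 FPKM (0.0424 for both). None of the entries of the annotated lncRNA table that carry a gene symbol passed; the symbol does not say which transcript of a locus was measured. HNRNPF had 212 ± 49.4 against 65.3 ± 27.4 FPKM (0.0858, from 0.0213 to 0.616 over the alternatives) and C3H1orf52 15.2 ± 7.73 against 49.6 ± 40.7 FPKM (0.282). The others, GNB2, LUZP1, JAM3, DMWD and RPL37A, had log2 differences from 0.34 to 1.49 and adjusted p from 0.208 to 0.770. In all, 11 of 453 passed, 6 higher and 5 lower, with 84 at an unadjusted p under 0.05. Limma called 0 after median centring (96 at an unadjusted p under 0.05), 0 without IVF 8-cell replicate 1 (47), 0 without SCNT 8-cell replicate 1 (87) and 0 without SCNT 8-cell replicate 2 (79), and 6, all lower, without IVF 8-cell replicate 2. The 4 named calls were lost without each of the 4 libraries, at adjusted p from 0.222 to 0.558 without IVF replicate 1, from 0.101 to 0.357 without IVF replicate 2, from 0.159 to 0.190 without SCNT replicate 1 and from 0.172 to 0.273 without SCNT replicate 2.

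Among numbered lncRNAs tested on their own, lnc_751, listed at 0 in IVF, was higher in SCNT, and lnc_750 and lnc_2437 (65.8 and 78.2 FPKM in IVF), both listed at 0 in SCNT, were lower (adjusted p = 0.0398 for all 3). Here lnc_2621 did not pass (0.0732). At the 4-cell stage, lnc_2437 was listed at 0 and 74.7 FPKM in the IVF replicates and at 0 and 33.5 FPKM in the SCNT replicates. A neighbour by number was above 0 exactly where lnc_2437 was at 0. Its zeros thus also separated replicates of the same group. In all, 4 of 1552 passed, 1 higher and 3 lower, with 375 at an unadjusted p under 0.05. The count was 89 without either IVF 8-cell replicate, with 88 and 89 of them lower, and limma called 0 without SCNT 8-cell replicate 1 (334 at an unadjusted p under 0.05) and 0 without SCNT 8-cell replicate 2 (313). The calls of lnc_751 and lnc_2437 were lost without IVF replicate 1 (0.0827 and 0.0502), IVF replicate 2 (0.0821 and 0.0544), SCNT replicate 1 (0.0936 for both) and SCNT replicate 2 (0.109 for both), and that of lnc_750 without IVF replicate 2 (0.0542), SCNT replicate 1 (0.103) and SCNT replicate 2 (0.109). The summed FPKM of numbered lncRNAs was 18029 and 17731 in the IVF libraries and 7957 and 9156 in the SCNT libraries. The 10 most abundant in each library held 52.1% and 41.8% of these sums in IVF and 36.6% and 35.6% in SCNT. Without them the sums were 8639 and 10326.5 in IVF and 5043 and 5901 in SCNT.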

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

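Tests of the read totals, of the collagen ratio between replicates and of annotated lncRNAs at matched level were chosen only after the result was seen. The lncRNAs whose change from 4 to 8 cells differed between SCNT and IVF embryos were picked out by a test of that difference itself. Of 2611 tested, 15 passed, 8 with a positive and 7 with a negative difference, SCNT change minus IVF change. The named ones were lnc_751 (difference of the log2 changes 7.43, adjusted p = 0.00653), lnc_1896 (5.46, 0.0313), lnc_750 (−7.44, 0.00653) and lnc_1448 (−7.07, 0.00653). These are fitted values that depend on the pseudocount and not folds or bounds, since each of the 4 was listed at 0 in whole groups. At 8 cells lnc_751 was listed above 0 in SCNT embryos alone and lnc_1448 in IVF embryos alone. lnc_1896 went from 0.847 and 0.793 FPKM to 0 in IVF and from 0 to 6.08 and 10.1 FPKM in SCNT. lnc_750 was listed at 0 in the SCNT 8-cell libraries alone, the only ones with lnc_751 above 0. In IVF embryos lnc_750 went from 37.4 and 45.5 to 67.8 and 106 FPKM. In SCNT embryos lnc_750 stood at 44.4 and 39.7 FPKM at 4 cells and lnc_751 at 106 and 68.7 FPKM at 8 cells. Taken as a pair they changed alike in both embryo types, so their opposite differences could lie in which of them received the reads. In limma the count was 0 without IVF 4-cell replicate 2 (351 at an unadjusted p under 0.05), 0 without SCNT 4-cell replicate 2 (279), 1 without SCNT 4-cell replicate 1, 71 and 57 without IVF 8-cell replicates 1 and 2, and 75 and 47 without SCNT 8-cell replicates 1 and 2.

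More genes were higher than lower in 8-cell SCNT embryos, 311 against 87, or 463 against 72 with protein-coding genes alone tested. The excess among calls was not kept without SCNT 8-cell replicate 2, where the median log2 difference over all tested genes was 0.33. Deeper SCNT libraries are argued against, since the largest total of the 4 libraries, 30.3 M reads, belongs to an IVF library. A few very abundant genes taking a larger share of the IVF libraries may account for part of it: the 10 most abundant genes imply a shift of 0.10 log2 and the 50 most abundant 0.13, against a median of 0.39, and after median centring 61.2% of the calls were still higher (44.6%, 121 against 150, after quantile normalization). Fibroblast RNA in the SCNT samples was not decided: the highest collagen gene there, COL1A2, reached 6.41 FPKM, against 3.22 and 2.44 FPKM in IVF, but DCN, a more abundant marker, was at 36.7 FPKM in SCNT and 89.9 FPKM in IVF, and 13 of 15 tested markers did not pass. A difference between SCNT and IVF embryos themselves stays open and was not tested.

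Many numbered lncRNAs were at 5 FPKM or more in some library and listed at 0 in another, 291 of 587 (49.6%), against 9 of 184 annotated lncRNAs (4.89%). Annotated lncRNAs weighted to the same highest FPKM were at 0 in 5.45%, less often than sampling that depends on FPKM alone would give. The classes were matched on FPKM and not on length, reads or molecules. Sampling of few molecules in the numbered lncRNAs could therefore not be decided. Expression that differs between groups may contribute: zeros filled whole groups 1.67 times as often as when placed at random (26 against 15.5 lncRNAs), although 254 of the 291 (87.3%) had a group with 1 replicate at 0 and the other at 1 FPKM or more. Neighbouring transcript models exchanging the reads of a locus may contribute as well, since 7.56% (22 of 291) had a neighbour by number that was above 0 exactly where they were at 0, against 0.412% at random. lnc_750 and lnc_751 are such a pair, so their opposite calls could be a change in which model received the reads.

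The library SCNT 8-cell replicate 2 stood apart from SCNT 8-cell replicate 1: 242 genes differed more than 4-fold between them, against 75 between the IVF replicates. A different depth is argued against, as the totals differed by 0.423%. Fibroblasts in replicate 2 are argued against, as its summed collagen level was 0.924 times that of replicate 1. A more advanced embryo could not be told apart from other causes: across lncRNAs, which are not independent replicates, its difference from replicate 1 correlated with the IVF stage change at r = −0.0378 (rho −0.0175, permutation p = 0.37), a negative value no farther from 0 than chance gives. No library batch is given in the labels, and a difference between the embryos sampled was not tested.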

How the results depend on the processing

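Library weights, protein-coding genes alone and lncRNAs above 0 in all 8 libraries were chosen only after the result was seen. For the 8-cell messenger RNAs, the count of 398 became 133 with a filter of 5 FPKM, 1327 after rescaling to a total of 1000000, 1924 with the replicate number as a block and 599 with library weights. Without a filter limma called 0 (3661 at an unadjusted p under 0.05), with 20289 genes tested in place of 10303. Leaving out each library gave 46 to 3834. It stayed within 1.5 times with a pseudocount of 0.1, centring, quantile normalization, no trend and protein-coding genes alone. KDM5B did not pass in any alternative and has no value with the 5 FPKM filter. Its log2 difference ranged from 0.60 to 1.76. Of the lists, 3 passed; with an estimated correlation camera called 0 (0 at an unadjusted p under 0.05), fry called 0 (13), and leaving out each library gave 1 to 7.

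The 8-cell lncRNA count of 124 became 13 without a filter, 79 with a filter of 1 FPKM, 75 after quantile normalization, 56 without a trend, 12 with the block and 75 for lncRNAs above 0 in all 8 libraries, 21 of them shared. With only the 2 compared groups limma called 0 (463 at an unadjusted p under 0.05). Leaving out each library gave 4 to 149. The 4-cell count of 11 became 6 without a filter, 7 with the block, 1 above 0 in all 8 and 3 with only the 2 groups, with 0 shared in both, and 0 to 27 when each library was left out.

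The IVF stage count of 38 became 7 without a filter, 10 at 1 FPKM, 13 without a trend, 1 with the block, 10 above 0 in all 8 (3 shared) and 1 with only the 2 groups (0 shared), and 4 to 78 when each library was left out. The SCNT stage count of 22 became 43 with a pseudocount of 0.1, 8 without a filter, 14 at 1 FPKM, 36 after centring, 38 after quantile normalization, 14 without a trend and 8 with the block. For it limma called 0 above 0 in all 8 (112 at an unadjusted p under 0.05) and 0 with only the 2 groups (269), and 3 to 71 when each library was left out. The interaction count of 15 became 5 with a pseudocount of 1, 4 without a filter, 23 after quantile normalization, 3 with the block and 0 above 0 in all 8 (144 at an unadjusted p under 0.05, limma), and 0 to 75 when each library was left out.

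The annotated count of 11 became 31 at 1 FPKM, 7 after quantile normalization and 42 with the block. Limma called 0 without a filter (85 at an unadjusted p under 0.05), 0 after centring (96) and 0 without a trend (83), and leaving out each library gave 0 to 6. The numbered count of 4 became 151 with a pseudocount of 0.1 and 57 at 1 FPKM. Limma called 0 without a filter (364) and 0 with the block (318), and leaving out each library gave 0 to 89. The causes of these changes in count were not tested. The filters change the number tested, but that was not their only effect. Without a filter, 20289 messenger RNA genes were tested in place of 10303, and the adjusted p of CCR7 in limma went from 0.014 to 0.242. The added tests alone could not raise it that far.

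Among the named genes and the lists that passed, 644 values under alternatives kept their direction and their side of the threshold. Another 165 kept the direction and lost the call, 4 gained a call (HNRNPF and lnc_2621 in the separate tables, 2 each) and 0 reversed. The 644 include values of genes that did not pass in either fit. The naming rule admitted only genes without overlap between groups. Their direction could therefore reverse only where the libraries were scaled anew, so the 0 says little about direction. In simulated data with equal spread in every library and no zeros, 74% of messenger RNAs and 38% of lncRNAs changed 4-fold were found. Both shares are for the 8-cell stage, and smaller changes were not simulated.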

Other observations

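The tests of neighbouring genes, with and without chromosome 29, were chosen only after the result was seen. Genes known only by a LOC number make up 53 of the 87 genes lower in 8-cell SCNT embryos (60.9%), against 45 of the 311 higher genes (14.5%) and 13.6% of all tested genes. Pseudogenes make up 11 of the 87. The 2 SCNT libraries differed in these falls: 45 of the 53 were higher in replicate 2 than in replicate 1 (median log2 difference 0.95). Of 26 lower genes with a symbol, 10 were (median −0.18). On chromosome 29, 10 of 12 neighbouring tested genes fell. These genes were singled out after their values were seen. LOC108634189 stood at 2475 and 1503 FPKM in IVF and 19.4 and 140 FPKM in SCNT (log2 difference −5.17 ± 0.79 SE, adjusted p = 0.0263), and LOC102190105 at 524 and 322 and at 9.80 and 61.0 FPKM (−3.99). The other 2, LOC102177051 (−1.47, 0.126) and LOC102190382 (−2.30, 0.0619), did not pass. All 10 fell after centring, after quantile normalization and without IVF 8-cell replicate 1, IVF 8-cell replicate 2 or SCNT 8-cell replicate 1, and 7 fell without SCNT 8-cell replicate 2 (adjusted p from 0.00911 to 0.0805).

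LOC-numbered lower genes had a lower gene next to them 15.3 times as often as when the calls were moved at random among LOC-numbered genes (21 of 50 against 1.37 expected). The count was made on the same calls that prompted it, so it describes them and is no independent test. Without chromosome 29 it was 12 of 39 against 0.926 expected. LOC-numbered higher genes also had a higher gene next to them more often, 4.78 times (11 of 44 against 2.30 expected). Over all placed genes the ratios were 20.8 for lower genes (23 against 1.11 expected) and 1.48 for higher genes (27 against 18.2 expected). Reads shared between similar neighbours could give the same picture and could not be tested without sequences, and whether the genes belong to families was not tested. The order of genes comes from the RefSeq table.

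Numbered lncRNAs shifted lower in SCNT than protein-coding genes drawn at the same level: the median log2 difference was −0.46, against 0.67 for the matched genes (0.60 to 0.73 over the draws). The gap was −1.13, −1.14 after centring or quantile normalization, and from −1.30 to −1.0 when each 8-cell library was left out. Centring moves all features of a library alike apart from the pseudocount, so it could hardly change the gap. For annotated lncRNAs the median was −0.11 against 0.62.

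No joint change was found between annotated lncRNAs and the nearest protein-coding gene that does not overlap them (rho = 0.0709 over 350 pairs, permutation p = 0.185, adjusted 0.315). The stage changes of IVF and SCNT embryos were nearly uncorrelated across 2611 lncRNAs (r = 0.0158, rho = 0.0158; 0.0906 over the 1119 above 0 in all 8 libraries). With 0.169 higher and 0.0230 lower shared calls expected by chance, the 0 that were shared decide nothing. The difference between SCNT and IVF at 8 cells correlated with that at 4 cells at r = 0.16 (rho = 0.17; 0.26 over the same 1119), with 1 higher and 2 lower calls shared, against 0.0896 and 0.163 expected by chance. Genes and lncRNAs are not independent replicates.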
